A study of Homo sapiens with 15 samples.

How the data were processed

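Total RNA from human epidermal keratinocyte cultures was labelled with biotin and measured on Affymetrix arrays, 15 in all, with 1 array for each of 3 groups at each of 5 times. Per the labels, the cells were moved to a medium without growth factor and pituitary extract supplements a day before treatment. They then received retinoic acid at 1 µM, 3,3',5-triiodothyronine (T3) at 1 mM diluted in sodium hydroxide, or no treatment. Whether the untreated cultures received the solvents is not given in the sources used here, so a solvent effect would be part of each difference from control. The T3 dose is given as the labels state it. It is far above the doses usual in culture, and whether its unit is right was not settled here, which limits what an absence of T3 calls means.

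The deposited values are linear probe set signals of the unit intensity, 1 column per array and 22277 probe sets per column. In every column the mean left after trimming 2% of values at each end was between 149.955 and 149.960, as a global scaling to a common target gives. The authors' software for summarising the probes is not given in the sources used here. The median log2 signal of the 15 arrays lay between 5.25 and 5.52, so the scaling was kept as deposited. Signals under the 20th percentile of all values pooled, 7.02, were raised to that floor, and values were then taken to log2. A change of a gene that sits at the floor in one group is understated by this step.

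Control probe sets, 62 in number, were left out. Of the others, 19064 matched a single gene, 1043 matched several and 2108 matched none in the table of probe sets used here. The last 2 kinds were kept out of the gene tests. For 19052 of the single-gene probe sets the symbol was the one the reference gene table pairs with the gene number, and for 12 it was not. The brightest probe set stood for each gene, which gave 11963 genes. Genes with a mean log2 signal at or above the 40th percentile of genes, 5.09, were tested. That left 7178 genes and removed 4785. Genomic positions were not used.

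The times stood in for replicates, because each group had 1 array per time. For retinoic acid (RA) against control, T3 against control and RA against T3, limma fitted all 15 arrays with group and time as terms, which asks for a shift that holds over the times. A second limma fit gave each treatment its own term for the early times, 1 and 4 h, and the late times, 24, 48 and 72 h, and the difference between late and early effects. Another fit, with group and phase as terms, compared late with early times over the 3 groups. P-values were adjusted by Benjamini and Hochberg over the 7178 genes, and a gene was taken as changed at an adjusted p under 0.05. These p-values measure only the spread between these arrays, and cultures from other donors were not sampled as far as the labels tell. The 15 pairs of arrays of different groups at the same time had correlations, after removal of group and gene means, between -0.11 and 0.63, with a median of 0.23, against a median of -0.09 for the 60 pairs that shared neither. Errors are standard errors of the limma fit, with 5 arrays per group over all times, 3 per group for late and 2 for early times. Their spread is 1 estimate per gene shared by the 3 groups, not that of the compared groups alone. The number of arrays limits the precision.

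Gene lists, 37 with 736 genes, covered responses to both hormones, epidermal differentiation, lipid synthesis, the cell cycle, stress, signalling, and markers of other cell types. Of their genes 498 were tested, and the 34 lists with at least 3 tested members went into camera of limma with a preset correlation of 0.01. The p-values were adjusted over the 34 lists within a comparison. Camera with an estimated correlation and fry were run beside it. With the preset correlation 58 list comparisons passed, and with an estimated correlation 0 did, so each list that passed is given with both.

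The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. For RA, T3 and RA against T3 over all times and for time in culture, the rule took up to 8 genes higher and 8 lower with the largest change among genes past the threshold with 1 sign at every time, or in every group for time in culture. It added up to 4 passing members of each list that camera called, and a set of retinoid, thyroid hormone and keratin genes given in any case. For early and late effects it took up to 5 genes per direction. Where fewer than 3 genes passed, it took up to 4 genes per direction with the smallest p, given as values and not as changes. Passing members of lists in the early and late effects, up to 4 per list, were added by the same rule after their values were seen. Genes of the fixed set below the brightness filter were taken from a fit without it.

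Calls were tested on simulated data with the spread of these arrays. A log2 shift of 1 was recovered for 83.0% of genes for RA and 81.8% for T3 over all times, 54.8% for late RA and 90.6% for time in culture. A shift of 0.5 was recovered for 20.6%, 19.4%, 2.80% and 40.2%. False genes made up 4.45%, 5.59%, 5.39% and 4.03% of those called. The simulated noise was independent between arrays, while the real arrays of the same time shared part of their variation. The shares for time in culture, 90.6%, 40.2% and 4.03%, may therefore not hold for the real calls. A list of 20 genes shifted by 0.5 was called in 10 of 10 simulations, and 4 of 200 unshifted lists reached an unadjusted p under 0.05. These lists held genes drawn at random, with noise independent between genes. They therefore do not show how often camera with the preset correlation errs for lists of genes that vary together.

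Alternatives were quantile normalization, no filter or a stricter one, a higher floor, the mean of a gene's probe sets, a variance trend with a robust fit, no time term or a random one, fits of the compared groups alone, log2 of time, and leaving out each array or time. Fits were made in R 4.3.3 with limma 3.58.1, and plots in Python 3.11.15 with matplotlib 3.10.9.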

Results

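Gene expression was measured in cultured human epidermal keratinocytes, the main cell type of the epidermis, on 15 arrays. The cultures were untreated, treated with retinoic acid (RA), a vitamin A derivative that acts through nuclear receptors, or treated with the thyroid hormone T3, which acts through related receptors. Each group had 5 arrays, taken at 1, 4, 24, 48 and 72 h, with no replicate of a group and time. The comparisons ask which genes each hormone changed, when, and where both hormones differed. The median signal per array lay between 38.0 and 45.9, and between 16.5% and 23.02% of signals were at the floor. The log2 ratio of 3' to 5' probe sets lay between 0.25 and 1.04 for ACTB and between -0.04 and 0.34 for GAPDH, with the RA array of 48 h highest for both. The first 4 principal components of the tested genes held 30.3%, 22.7%, 9.28% and 7.15% of the variance.

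Over all times RA raised ID1, an inhibitor of differentiation factors, by a log2 change of 2.88 ± 0.15 (SE, 5 arrays per group), with a difference from control between 2.50 and 3.36 at each time. HCAR3, a receptor for hydroxylated fatty acids, rose by 3.56 ± 0.38, ELF3, an epithelial transcription factor, by 2.69 ± 0.33, and RHCG, an ammonia transporter, by 2.78 ± 0.36. The epithelial genes CLCA4 and CEACAM6 rose by 4.55 ± 0.98 and 2.54 ± 0.69, the cytokine IL1B by 2.71 ± 0.47 and the protease inhibitor SERPINB1 by 2.66 ± 0.55. Genes of the outer epidermal layers fell, with log2 changes of -4.37 ± 1.09 for the envelope precursor SPRR2B, -4.00 ± 1.06 for TGM1, which crosslinks the cornified envelope, and -3.61 ± 0.91 for the desmosomal cadherin DSG1. Further falls were -3.07 ± 0.70 for CLIC3, -2.72 ± 0.69 for the calcium pump ATP2C2, -2.71 ± 0.32 for ODC1, which makes polyamines, -2.27 ± 0.57 for the water and glycerol channel AQP9 and -2.27 ± 0.43 for the vesicle transport gene EXPH5. Of the genes past the threshold with 1 direction at all 5 times, as the rule required, these 16 had the largest changes. TGM1 and AQP9 were at the floor in 2 of the 3 late RA arrays and ATP2C2 in 1, so their falls are understated.

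In limma 531 of 7178 genes passed under RA over all times, 235 higher and 296 lower, and 1918 had an unadjusted p under 0.05 where 358.9 were expected by chance. Of those called, 75 rose and 86 fell at least 2-fold. The smallest limma adjusted p, 3.83e-06, was that of ID1, and among the 16 genes the largest was 0.0486, for CEACAM6. The count was 328, 112, 85 or 123 without the control array of 4, 24, 48 or 72 h, and 1094, 233, 141 or 195 without the RA array of 1, 24, 48 or 72 h. It was 325 without the T3 array of 48 h, and 349, 68, 25 or 71 without the time of 4, 24, 48 or 72 h. With no filter 310 genes passed, without the time term 226, and with RA and control arrays alone 17.

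The list of textbook targets of the retinoic acid receptors (RAR) had a higher median under RA. Of 13 tested members 4 rose, and adjusted over the list alone 7 rose and 1 fell, with a median log2 change of 0.74 (camera of limma, adjusted p = 0.000218, and adjusted p = 0.0658 with an estimated correlation). The risers were ELF3, DHRS3, which reduces retinal, by 1.82 ± 0.18, the nuclear receptor corepressor NRIP1 by 1.53 ± 0.15, and SMAD3 by 1.10 ± 0.13, where 1 of 3 other SMAD3 probe sets had the opposite sign. Other genes that were fixed as retinoid markers did not pass in limma: CRABP2, a retinoic acid binding protein, had -0.77 ± 0.25 (adjusted p = 0.0798), TGM2 -0.64 ± 0.40 (adjusted p = 0.336) and PLAAT4 1.01 ± 0.31 (adjusted p = 0.0699). CYP26A1, which breaks down retinoic acid, RARB and RARRES1 were too dim for the filter. Without the filter limma gave CYP26A1 0.18 ± 0.37 with 7 of 15 arrays at the floor, RARB 0.54 ± 0.35 and RARRES1 0.20 ± 0.38, with adjusted p of 0.856, 0.435 and 0.850. RARB signals at 24, 48 and 72 h were 17.1, 56.5 and 68.9 in RA and 32.6, 21.6 and 21.8 in control. Those of RARRES1 were 35.9, 57.3 and 139.7 in RA and 34.2, 37 and 56.1 in control.

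Of 24 genes of the terminal differentiation keratins and the cornified envelope 7 fell under RA over all times and 0 rose, and adjusted over the list alone 15 fell. Their median was -1.14 (camera of limma, adjusted p = 2.83e-05, and adjusted p = 0.647 with an estimated correlation). Beside SPRR2B and TGM1, the suprabasal keratin KRT10 fell by 1.58 ± 0.37 and TGM3 fell by 1.29 ± 0.34. KRT1, the partner of KRT10, had -3.83 ± 1.11, FLG, the filaggrin precursor, -2.75 ± 0.79, LORICRIN -2.31 ± 1.00 and IVL, the involucrin gene, 0.46 ± 0.21, and none of these 4 passed in limma over all times (adjusted p of 0.0578, 0.0576, 0.168 and 0.183). Keratins of mucosal and simple epithelia went the other way: KRT19 rose by 3.34 ± 0.87, KRT7 by 2.32 ± 0.48 and KRT13 by 1.49 ± 0.25, while KRT4 had 0.57 ± 0.59. That list of 6 had a median of 1.03 and did not pass (camera of limma, adjusted p = 0.0998).

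The lists of the epidermal lipid barrier and of cholesterol biosynthesis had lower medians under RA. Of 11 epidermal lipid barrier genes 2 fell, the lipoxygenases ALOX12B at -4.18 ± 1.12 and ALOXE3 at -1.60 ± 0.39, and adjusted over the list alone 8 fell and 1 rose (camera of limma, median -0.98, adjusted p = 0.0113, and adjusted p = 0.647 with an estimated correlation). Of 18 genes of cholesterol biosynthesis 7 fell and 1 rose, and adjusted over the list alone 13 fell and 1 rose (camera of limma, median -0.58, adjusted p = 1.46e-05, and adjusted p = 0.429 with an estimated correlation). MVD, HMGCS1 and LSS fell, with log2 changes of -1.41 ± 0.34, -1.30 ± 0.20 and -0.75 ± 0.17, while SC5D rose by 0.91 ± 0.24. Of 10 fatty acid synthesis genes 1 was higher and 0 lower in limma, with 3 lower at an unadjusted p under 0.05, and the list did not pass (camera, median -0.21, adjusted p = 0.537). At 1 h the medians of the barrier and cholesterol lists were 0.062 and 0.061. At each time from 4 h on they were negative.

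The list of metallothioneins and metal response genes had a median of -0.35 over 9 members (camera of limma, adjusted p = 0.0113, and adjusted p = 0.629 with an estimated correlation). The 1 member that fell, also adjusted over the list alone, was SLC30A1, a zinc exporter and no metallothionein, at -0.90 ± 0.14. The list stood at 0.098 at 24 h. Genes of the integrated stress response and the unfolded protein response had a median of -0.36 over 21 members. In limma 0 of them passed, also adjusted over the list alone, with 1 higher and 5 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.0326, and adjusted p = 0.647 with an estimated correlation). The list stood at 0.061 and 0.10 at 4 and 24 h. Of 3 markers of sweat and sebaceous glands 2 rose, also adjusted over the list alone, KRT7 and the lipid droplet protein PLIN2, the latter by 1.47 ± 0.20 (camera of limma, median 1.47, adjusted p = 0.0414, and adjusted p = 0.429 with an estimated correlation). KRT7 is also in the list of simple-epithelium keratins. Of 6 tested fibroblast markers 1 was lower and the list did not pass (camera of limma, median -0.12, adjusted p = 0.360).

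**Figure D1:**
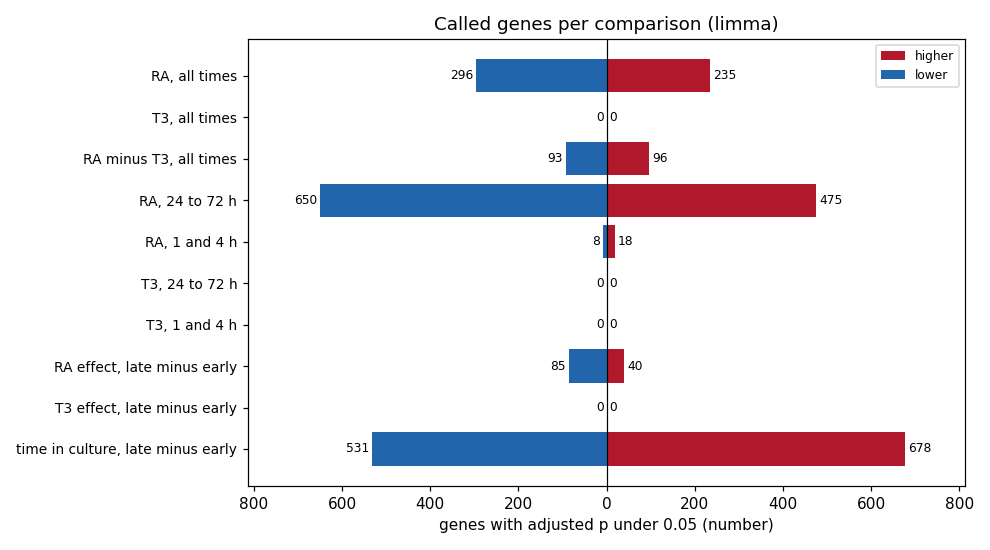
Number of genes with an adjusted p under 0.05 in limma for each comparison, with genes higher to the right of 0 and genes lower to the left. Late RA called 475 genes higher and 650 lower, early RA 18 and 8, and T3 0 in either direction over all times, early or late.

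**Figure D2:**
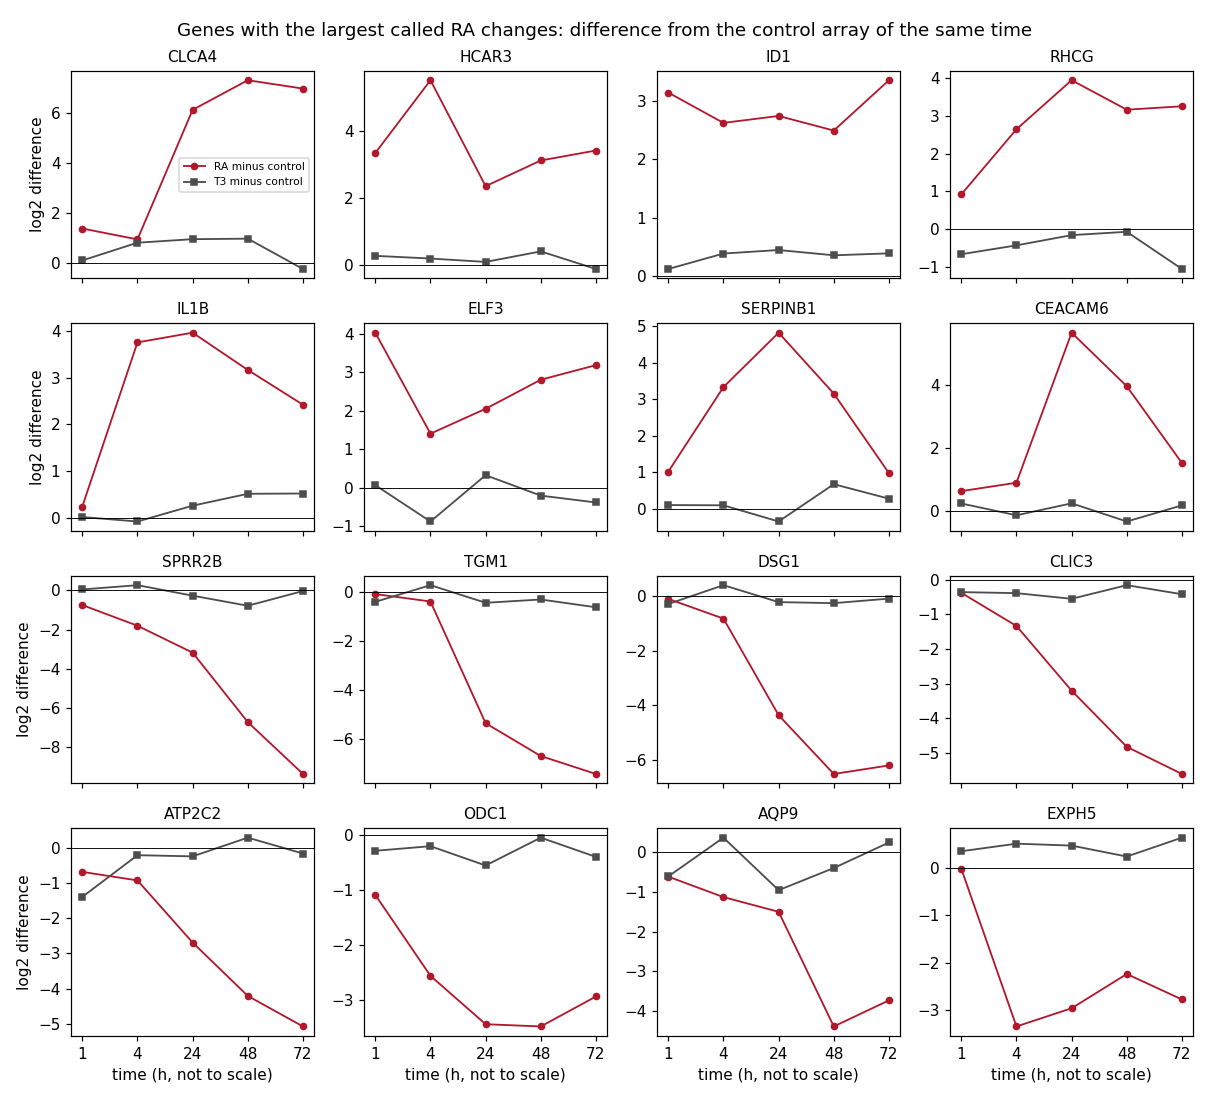
Log2 difference from the control array of the same time (vertical axis, scaled per gene) for the 16 genes with the largest RA changes, against time in h (horizontal axis, not to scale), with RA as red circles and T3 as grey squares. ID1 and HCAR3 were raised by RA from 1 h on, at 3.15 and 3.35, while TGM1 stood at -0.10 at 1 h and -7.44 at 72 h.

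At 24, 48 and 72 h RA lowered genes of the differentiating layers, whose list passed in camera with the preset correlation and not with an estimated one. TGM1 fell 90.8-fold, a log2 change of -6.50 ± 0.36 (SE, 3 arrays per group), and ALOX12B fell 111-fold, a log2 change of -6.79 ± 0.40. SPRR2B, KRT1 and the fatty acid hydroxylase CYP4B1 fell too, with log2 changes of -6.43 ± 1.01, -6.17 ± 0.65 and -6.12 ± 0.63. TGM1, ALOX12B and CYP4B1 were at the floor in 2 of the 3 late RA arrays, so these falls are understated. CLCA4 rose 112-fold by 6.80 ± 0.36, the simple-epithelium keratin KRT19 by 5.29 ± 0.40, the carbonyl reductase CBR3 by 3.83 ± 0.63 with 2 late control arrays at the floor, CEACAM6 by 3.72 ± 0.67 and the basal keratin KRT15 by 3.68 ± 0.56.

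In limma 1125 genes passed at these late times, 475 higher and 650 lower, with 2225 at an unadjusted p under 0.05, and 161 rose and 325 fell at least 2-fold. They included 414 of the 531 genes called over all times, with the same sign in each. The 3 late RA arrays had the 3 lowest median signals of the 15, 38.0, 38.0 and 39.1, and the RA array of 48 h had the most signals at the floor. The count was 573, 510 or 624 without the control array of 24, 48 or 72 h, 552 without the RA array of 48 h, and 210 or 490 without the time of 48 or 72 h.

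By list, 16 of 24 envelope and differentiation genes fell at late times and 0 rose, and adjusted over the list alone 19 fell (camera of limma, median -1.64, adjusted p = 1.85e-10, and adjusted p = 0.354 with an estimated correlation). CDSN, the corneodesmosin gene, fell by 5.20 ± 1.01. Of 11 lipid barrier genes 8 fell, 9 adjusted over the list alone (camera of limma, median -1.53, adjusted p = 8.88e-06, and adjusted p = 0.222 with an estimated correlation). Among them were ALOXE3 at -2.48 ± 0.17, the cholesterol sulfotransferase SULT2B1 at -2.37 ± 0.36 and the lipid transporter ABCA12 at -2.21 ± 0.41. Of 18 cholesterol genes 13 fell and 1 rose, 15 and 1 adjusted over the list alone (camera of limma, median -0.84, adjusted p = 4.55e-08, and adjusted p = 0.222 with an estimated correlation). TM7SF2, MVD and HMGCS1 fell, with log2 changes of -2.15 ± 0.18, -2.14 ± 0.30 and -1.72 ± 0.17, and SC5D rose by 1.27 ± 0.23. These falling groups were measured in the arrays with the lowest median signals.

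Of 19 genes of desmosomes and tight junctions 2 rose and 6 fell at late times, 3 and 8 adjusted over the list alone (camera of limma, median -0.32, adjusted p = 0.0397, and adjusted p = 0.521 with an estimated correlation). The cadherins DSG1 and DSC1 and the claudin CLDN1 fell, with log2 changes of -5.70 ± 0.42, -3.53 ± 0.28 and -2.25 ± 0.35, while CLDN7 rose by 2.85 ± 0.45. Of 18 serine proteases and protease inhibitors of the epidermis 1 rose and 8 fell, 1 and 9 adjusted over the list alone (camera of limma, median -0.69, adjusted p = 0.0233, and adjusted p = 0.729 with an estimated correlation). The protease KLK6 rose by 2.43 ± 0.43, and the inhibitors SERPINB4, SLPI and SERPINB8 fell, with log2 changes of -2.53 ± 0.49, -1.60 ± 0.40 and -1.32 ± 0.27. The RAR target list had 6 genes up and 1 down, 7 and 1 adjusted over the list alone (camera of limma, median 1.15, adjusted p = 0.0181, and adjusted p = 0.244 with an estimated correlation). STRA6, a receptor for retinol transport, rose by 3.25 ± 0.56, ELF3 by 2.68 ± 0.45, DHRS3 by 2.02 ± 0.22 and NRIP1 by 1.61 ± 0.21. KRT7 and PLIN2 of the 3 gland markers rose by 3.44 ± 0.29 and 1.16 ± 0.22, also adjusted over the list alone (camera of limma, median 1.16, adjusted p = 0.0298, and adjusted p = 0.309 with an estimated correlation), though PLIN2 had -0.000993 with the mean of its probe sets.

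Cell cycle genes had higher medians over the late times, though not at 72 h. By time the difference from control was 0.30, 1.11 and -0.0036 for G2/M and 0.69, 0.24 and 0.022 for G1/S at 24, 48 and 72 h. The RA array of 48 h had the highest 3' to 5' ratios of the 15, 1.04 for ACTB and 0.34 for GAPDH, and the most signals at the floor. For G2/M and mitosis 2 of 18 genes rose, also adjusted over the list alone, UBE2C by 1.12 ± 0.30 and HMMR by 0.83 ± 0.17 (camera of limma, median 0.50, adjusted p = 0.0181, and adjusted p = 0.691 with an estimated correlation). For G1/S and DNA replication RFC5 rose by 0.80 ± 0.18 and CCNE1, the cyclin E1 gene, fell by 1.55 ± 0.26, the only 2 of 22 that passed, also adjusted over the list alone (camera of limma, median 0.29, adjusted p = 0.0397, and adjusted p = 0.691 with an estimated correlation). Of 16 immediate early genes KLF4 and DUSP1 fell, at -2.46 ± 0.18 and -1.15 ± 0.15, also adjusted over the list alone (camera of limma, median -0.38, adjusted p = 0.0181, and adjusted p = 0.691 with an estimated correlation). Of 21 stress response genes 3 fell, 5 adjusted over the list alone (camera of limma, median -0.52, adjusted p = 0.00511, and adjusted p = 0.521 with an estimated correlation). They were ASNS and PHGDH, which make asparagine and serine, at -2.28 ± 0.63 and -1.07 ± 0.13, and HERPUD1 at -0.70 ± 0.20. In the metallothionein list of 9 genes SLC30A1 and the transcription factor MTF1 fell, also adjusted over the list alone, at -1.03 ± 0.19 and -0.69 ± 0.18 (camera of limma, median -0.31, adjusted p = 0.04996, and adjusted p = 0.691 with an estimated correlation). Of 22 ribosomal protein genes RPL18 rose by 0.65 ± 0.18, and 0 passed adjusted over the list alone (camera of limma, median 0.17, adjusted p = 0.0397, and adjusted p = 0.869 with an estimated correlation). At 24, 48 and 72 h the medians were 0.042, -0.62 and -0.97 for immediate early genes and 0.10, -0.60 and -0.68 for the stress response. They were 0.098, -0.47 and -0.63 for metallothioneins and -0.19, 0.092 and 0.60 for ribosomal proteins.

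At 1 and 4 h RA had already raised HCAR3 by 4.44 ± 0.50 (SE, 2 arrays per group) and ID1 by 2.89 ± 0.25. The mucosal keratin KRT4 rose by 2.52 ± 0.37 at these times, while its smaller change over all times, given above, did not pass. TTC9 and ABHD17B rose by 2.47 ± 0.30 and 2.35 ± 0.36, with 2 and 1 of the early control arrays at the floor. Under T3, against the same control arrays, ABHD17B had 2.07 ± 0.36 and did not pass in limma. The growth arrest gene GAS1 fell by 2.55 ± 0.43 with 1 early RA array at the floor. The transcriptional coregulator CITED2, the endothelin precursor EDN1 and the transcription factor KLF4 fell, with log2 changes of -2.13 ± 0.28, -1.76 ± 0.24 and -1.66 ± 0.22. ING4 fell by 1.75 ± 0.29, and its other probe set had the opposite sign.

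In limma 26 genes passed at the early times, 18 higher and 8 lower, and 806 had an unadjusted p under 0.05. Of the 26 genes 13 also passed at late times, 12 of them with the same sign. The RAR target list had a median of 0.54, 0 of 13 genes past the threshold over all genes, 4 up adjusted over the list alone and 5 higher at an unadjusted p under 0.05 in limma (camera, adjusted p = 7.48e-05, and adjusted p = 0.0823 with an estimated correlation). The mucosal keratins had a median of 0.52, with KRT4 the 1 of 6 that rose and 2 adjusted over the list alone (camera of limma, adjusted p = 0.0399, and adjusted p = 0.322 with an estimated correlation). At 1 and 4 h they stood at -0.041 and 1.14, and ribosomal proteins at -0.013 and -0.43. Both lists thus rested on the arrays of 4 h. In limma 0 genes passed in 3 other lists with lower medians. Basal keratins and hemidesmosome genes had -0.19, with 1 lower adjusted over the list alone and 2 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.0399, and adjusted p = 0.322 with an estimated correlation). Metallothioneins had -0.47, with 0 adjusted over the list alone and 2 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.0399, and adjusted p = 0.814 with an estimated correlation). Ribosomal proteins had -0.23, with 0 members at either threshold of limma, and -0.02 after quantile normalization, where the camera direction turned (camera, adjusted p = 0.0399, and adjusted p = 0.912 with an estimated correlation).

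The early count rested on single arrays. It was 16, 0, 5, 4 or 5 without the control array of 1, 4, 24, 48 or 72 h, 172, 9, 7 or 12 without the RA array of 1, 4, 48 or 72 h, and 9, 9, 11, 7 or 14 without the T3 array of 1, 4, 24, 48 or 72 h. Without the time of 1, 4, 24, 48 or 72 h it was 121, 0, 9, 4 or 7, with no filter 11 and with the mean of a gene's probe sets 10. Without the control array of 4 h the comparison called 0 genes in limma.

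T3, at a labelled dose of 1 mM that is far above those usual in culture, changed no gene past the threshold of limma. Over all times 0 genes passed and 782 had an unadjusted p under 0.05, against 358.9 expected by chance, and the smallest adjusted p was 0.183. The genes with the smallest p and 1 sign at all 5 times had log2 differences of 0.74 ± 0.13 for RAB5C, 0.53 ± 0.10 for WAC, 0.57 ± 0.11 for EI24 and 0.59 ± 0.12 for CDC42BPB. On the lower side were the cell surface gene TENM3 at -0.93 ± 0.15, GLUD1, the glutamate dehydrogenase gene, at -0.59 ± 0.10, TRIM8 at -0.75 ± 0.13 and the tyrosine kinase SRC at -1.98 ± 0.38. The other EI24 probe set had the opposite sign.

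Of 10 tested textbook thyroid hormone targets 0 passed in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and their median was 0.04 (camera, adjusted p = 0.689). HR, a corepressor induced by the hormone in other tissues, had 0.11 ± 0.20, the deiodinase DIO2 -0.14 ± 0.22, and the receptors THRA and THRB 0.24 ± 0.26 and 0.15 ± 0.27. KLF9, below the filter, had 0.61 ± 0.34 in a limma fit without it (adjusted p = 0.580). From 1 to 72 h its signal was 48.1, 30.1, 34.6, 34.5 and 21.7 in T3. In control it was 40.7, 19.5, 23.6, 20 and 12.1, lower at each time. THRSP and KRT6A had no probe set of their own. The keratins had -0.18 ± 0.12 for KRT5, -0.14 ± 0.14 for KRT14, -0.13 ± 0.18 for KRT16 and -0.19 ± 0.37 for KRT10. HR turned sign with the mean of its probe sets and without the control array of 1 h, DIO2 without the control or T3 array or the time of 4 h, THRB without the T3 array of 1 h and KRT10 without the control array of 48 h. None of these 8 genes passed in limma. The list of TGF-beta targets and extracellular matrix genes had a median of -0.19, with 0 of 31 members past the threshold of limma, also adjusted over the list alone, and 2 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.0396, and adjusted p = 0.824 with an estimated correlation).

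At late times 0 genes passed under T3 in limma, with 698 at an unadjusted p under 0.05. The smallest p were those of SASH3 at 1.01 ± 0.15, ANAPC15 at 0.85 ± 0.15, RABIF at 0.93 ± 0.17 and the growth factor TGFB3 at 1.91 ± 0.38, and on the lower side of the matrix protease MMP2 at -0.86 ± 0.13, PC at -2.03 ± 0.33, TENM3 at -1.11 ± 0.19 and IL6R at -0.90 ± 0.16. PC was at the floor in 2 late T3 arrays and TGFB3 in 1 late control array. The matrix list had a median of -0.24, with 1 member lower adjusted over the list alone (camera of limma, adjusted p = 0.00700, and adjusted p = 0.777 with an estimated correlation). At early times 0 genes passed in limma, with 463 at an unadjusted p under 0.05. The values were 2.92 ± 0.49 for the carbonic anhydrase CA1, 2.07 ± 0.36 for ABHD17B, 0.88 ± 0.18 for FBLN1 and 0.91 ± 0.20 for ZKSCAN4, and -1.92 ± 0.30 for SLC38A12, -1.29 ± 0.25 for TRMT13, -1.30 ± 0.25 for B4GALT1 and -0.88 ± 0.17 for ERBIN. CA1 and ABHD17B were each at the floor in 1 early control array. Leaving out 1 array or time gave 1 gene over all times without the T3 array of 72 h and 1 at late times without the T3 array of 24 h. At early times it gave 4 without the control array of 1 h, 1 without the RA array of 1 or 4 h and 2 without the time of 1 h. For T3 over all times, simulated log2 shifts of 1 were called for 81.8% of genes and shifts of 0.5 for 19.4%, so smaller shifts would mostly have been missed. The late and early T3 comparisons were not simulated. For late RA, with as many arrays as late T3, these shares were 54.8% and 2.80%. The median SE of the T3 comparisons was 0.17 over all times, 0.20 late and 0.24 early.

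The effect of RA differed between the late and the early times for CLCA4 and KRT19, which gained 5.63 ± 0.56 and 4.89 ± 0.63 over their early difference from control, and for the cytochrome CYP1B1 by 5.00 ± 0.55, RGCC by 3.55 ± 0.50 and the tubulin TUBA1A by 2.88 ± 0.41. It was lower late than early at -6.52 ± 0.64 for ALOX12B, -6.34 ± 0.99 for CYP4B1, -6.25 ± 0.57 for TGM1, -5.85 ± 1.03 for KRT1 and -5.52 ± 0.87 for LORICRIN, of which ALOX12B, CYP4B1 and TGM1 were at the floor in 2 late RA arrays and LORICRIN in 1. In limma 125 genes passed this test of the difference, 40 with a higher late effect and 85 with a lower one, and 1131 had an unadjusted p under 0.05. Part of the CYP1B1 difference lay at the early times. At 1 and 4 h its signal was 161.4 and 105.4 in RA, against 475.5 and 313.8 in control. Of the 125 genes 119 were also called at late times. The count was 44, 29, 50, 40 or 52 without the control array of 1, 4, 24, 48 or 72 h, 352 or 45 without the RA array of 24 or 48 h and 80 without the T3 array of 48 h. It was 68, 34, 13 or 45 without the time of 1, 4, 48 or 72 h, and 53 with no filter.

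For T3 the difference between late and early effects called 0 genes in limma, with 278 at an unadjusted p under 0.05 and 358.9 expected by chance. The genes with the smallest p had 1.16 ± 0.22 for ZNF26, 1.21 ± 0.23 for CYB5R4, 3.37 ± 0.70 for DECR2 and 1.10 ± 0.24 for SASH3, and -2.48 ± 0.46 for ABHD17B, -1.36 ± 0.31 for TOP3B, -1.56 ± 0.40 for RBBP5 and -2.46 ± 0.64 for CA1. The other TOP3B probe set had the opposite sign. Without the control array of 1 h 2 genes passed, and without the time of 1 h 1.

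RA and T3 were compared with each other in the fit of all 15 arrays. KRT19 was higher with RA by 3.93 ± 0.87 (SE, 5 arrays per group), HCAR3 by 3.38 ± 0.38, RHCG by 3.24 ± 0.36, ELF3 by 2.91 ± 0.33, KRT7 by 2.67 ± 0.48, the cytokine LIF by 2.59 ± 0.45, ID1 by 2.54 ± 0.15 and SERPINB1 by 2.49 ± 0.55. LIF was at the floor in 1 late T3 array. Lower with RA were EXPH5 at -2.71 ± 0.43, ODC1 at -2.41 ± 0.32, KLF4 at -2.37 ± 0.18, CLDN1 at -2.25 ± 0.35, the estrogen sulfotransferase SULT1E1 at -2.18 ± 0.47, RCAN1, an inhibitor of calcineurin, at -2.17 ± 0.32 and the epidermal transcription factor OVOL1 at -1.99 ± 0.33. CHI3L1 was at -2.47 ± 0.56, with all 3 late RA arrays at the floor.

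In limma 189 genes differed between both hormones, 96 higher with RA and 93 lower, and 1651 had an unadjusted p under 0.05. Of the 189, 141 were also called for RA against control, all with the same sign, in comparisons that share the 5 RA arrays. The count was 104, 88, 85 or 89 without the control array of 4, 24, 48 or 72 h, 957, 70, 55 or 67 without the RA array of 1, 24, 48 or 72 h, and 75, 54, 56 or 66 without the T3 array of 4, 24, 48 or 72 h. Without the time of 1, 4, 24, 48 or 72 h it was 638, 71, 36, 30 or 46. It was 44 with no filter, 298 with the stricter filter, 289 with a variance trend, 93 without the time term, 342 with a random one and 10 with RA and T3 arrays alone.

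Between RA and T3, 4 of 13 RAR targets were higher, and adjusted over the list alone 8 were higher and 1 lower (camera of limma, median 0.68, adjusted p = 0.000246, and adjusted p = 0.0684 with an estimated correlation). Beside ELF3 these were DHRS3 at 1.86 ± 0.18, NRIP1 at 1.52 ± 0.15 and SMAD3 at 0.68 ± 0.13. Of 6 mucosal keratins KRT19, KRT7 and KRT13 were higher, also adjusted over the list alone, KRT13 by 1.49 ± 0.25 (camera of limma, median 0.83, adjusted p = 0.00465, and adjusted p = 0.104 with an estimated correlation). Of 24 envelope genes TGM3 and SPRR1A were lower at -1.67 ± 0.34 and -1.17 ± 0.26, and adjusted over the list alone 15 were lower and 1 higher (camera of limma, median -1.07, adjusted p = 3.77e-05, and adjusted p = 0.574 with an estimated correlation). Of 11 lipid barrier genes ALOXE3 was lower at -1.68 ± 0.39, and 7 adjusted over the list alone (camera of limma, median -1.19, adjusted p = 0.00465, and adjusted p = 0.574 with an estimated correlation). Of 18 cholesterol genes PMVK was lower at -0.68 ± 0.15, and adjusted over the list alone 10 were lower and 1 higher (camera of limma, median -0.47, adjusted p = 0.000246, and adjusted p = 0.574 with an estimated correlation). In the serine protease list KLK6 was higher at 1.99 ± 0.32 and SERPINB5 lower at -0.66 ± 0.14, with 2 higher and 8 lower adjusted over the list alone (camera of limma, median -0.53, adjusted p = 0.0338, and adjusted p = 0.722 with an estimated correlation).

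RFC5 was the 1 of 22 G1/S genes that was higher with RA than with T3, at 0.61 ± 0.13, and 2 were adjusted over the list alone (camera of limma, median 0.30, adjusted p = 0.0148, and adjusted p = 0.679 with an estimated correlation). PLIN2 at 1.65 ± 0.20 and KRT7 were higher of the 3 gland markers, also adjusted over the list alone (camera of limma, median 1.65, adjusted p = 0.00413, and adjusted p = 0.104 with an estimated correlation). In limma 0 genes passed in 3 further lists, also adjusted over the list alone. The G2/M list had a median of 0.38 with 4 higher at an unadjusted p under 0.05 (camera, adjusted p = 0.00217, and adjusted p = 0.574 with an estimated correlation). The interferon list had 0.22 with 1 higher (camera, adjusted p = 0.0399, and adjusted p = 0.771 with an estimated correlation). The stress response list had -0.39 with 8 lower (camera, adjusted p = 0.00465, and adjusted p = 0.574 with an estimated correlation).

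Across the 7178 genes the changes under RA and T3 had a correlation of 0.302. Both use the same control arrays, and simulated groups without any effect gave a mean of 0.499, from 0.453 to 0.536. The covariance was 0.0371, against 0.0245 in the simulations. With the times split so that no control array was shared, the mean correlation over 20 splits was 0.150, from 0.00778 to 0.274, and the covariance 0.0240. With no filter the correlation was 0.392. These values are across genes, which are not independent replicates. No call was shared, since T3 called 0 genes in limma, with 782 at an unadjusted p under 0.05.

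**Figure D3:**
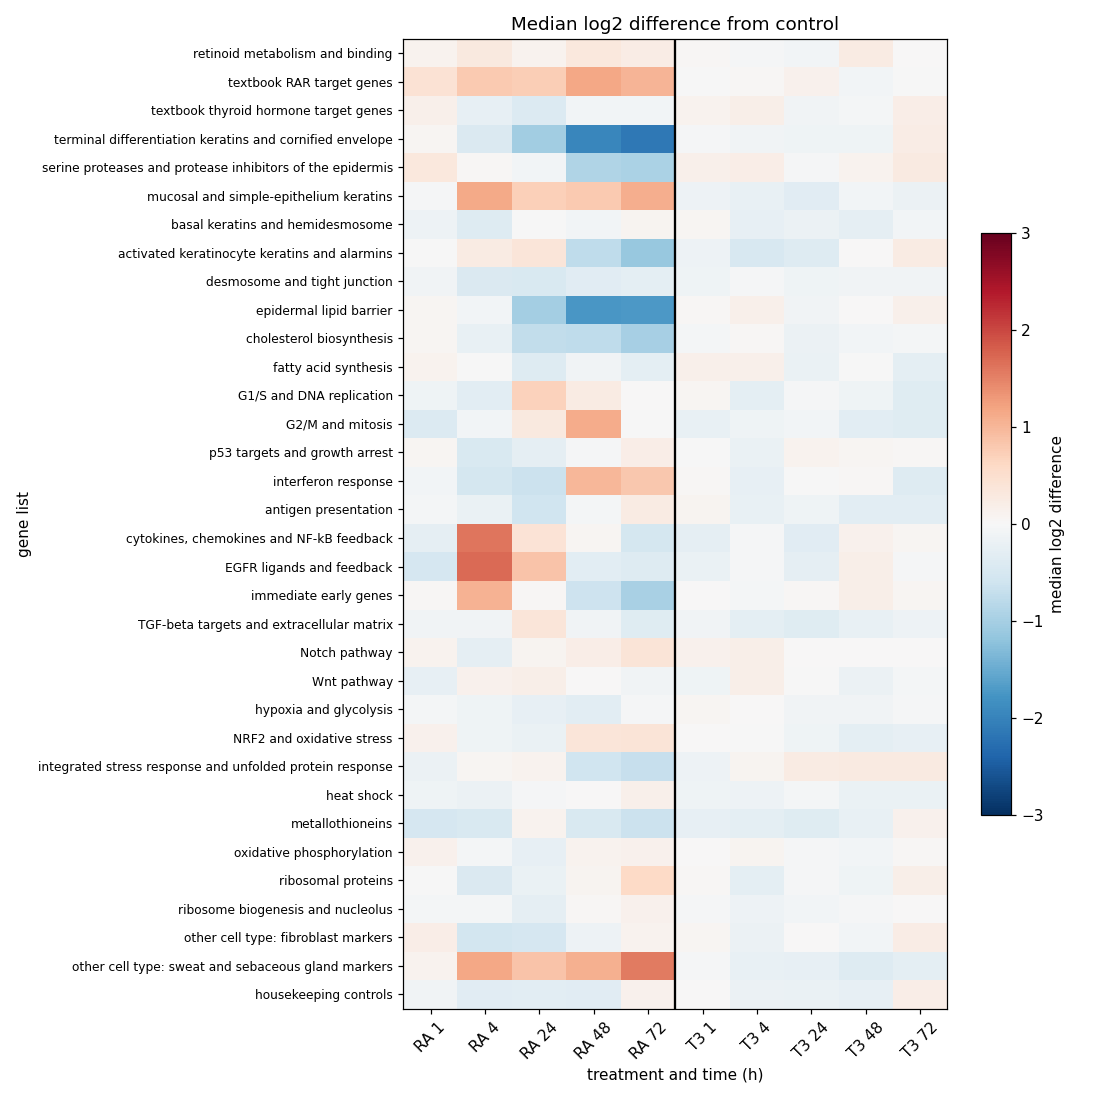
Median log2 difference from the control array of the same time for each of 34 gene lists (vertical axis), under RA and T3 at 1 to 72 h (horizontal axis), in red where higher and blue where lower. The list of terminal differentiation keratins and cornified envelope darkens from RA at 24 h to RA at 72 h, and stays pale under T3.

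Genes also changed with time in culture in a fit of the 3 groups. Between the early and the late times CYP1A1, a target of the aryl hydrocarbon receptor, fell by 4.95 ± 0.39 (SE, 6 early and 9 late arrays). The reductases AKR1B10 and AKR1C2 fell, with log2 changes of -2.77 ± 0.33 and -2.39 ± 0.41. So did CDHR1 at -3.14 ± 0.66, WNT4 at -3.07 ± 0.68, the growth factor carrier FGFBP1 at -2.84 ± 0.57, IGFBP5 at -2.49 ± 0.49 and ARHGDIG at -2.39 ± 0.45. WNT4 was at the floor in all 3 late RA arrays, CYP1A1 and CDHR1 each in 3 late arrays and IGFBP5 in 2, so these falls are understated. ID4 rose by 3.02 ± 0.62, the surface protease FAP by 2.96 ± 0.40 with 2 early control arrays at the floor, the hair follicle protein TCHH by 2.88 ± 0.42, ADAMTS1 by 2.88 ± 0.31, the matricellular gene CCN2 by 2.83 ± 0.59, the protease inhibitor CST6 by 2.61 ± 0.30, the cyclin CCNA1 by 2.58 ± 0.43 and CEACAM6 by 2.55 ± 0.61.

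In limma 1209 genes passed with time in culture, 678 higher and 531 lower, and 2380 had an unadjusted p under 0.05. Of the 1209 genes 222 were also called for late RA, 155 with the same sign, in comparisons that share the late arrays. The count was 556, 352 or 556 without the time of 4, 48 or 72 h and 4 with the 5 control arrays alone. Arrays of different groups at the same time shared part of their variation, so these p-values may be too small.

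The lipid synthesis lists had lower medians late than early in culture. From 1 to 72 h the cholesterol list had median levels of 9.02, 9.10, 9.22, 8.46 and 8.41 in control. It had 8.79, 9.46, 9.15, 8.44 and 8.15 in T3 and 9.15, 9.12, 8.20, 7.87 and 7.49 in RA. At 24 h it lay under its 1 h level only in RA, so the fall averaged over groups holds part of the RA effect. Of 18 cholesterol genes 8 fell, 10 adjusted over the list alone (camera of limma, median -0.55, adjusted p = 0.000115, and adjusted p = 0.411 with an estimated correlation), with MVD at -1.62 ± 0.44, LSS at -1.59 ± 0.23, HMGCS1 at -1.29 ± 0.25 and ACAT2 at -0.86 ± 0.21. Of 10 fatty acid synthesis genes 6 fell, 8 adjusted over the list alone (camera of limma, median -0.74, adjusted p = 6.14e-05, and adjusted p = 0.277 with an estimated correlation). Among them were the regulator SREBF1 at -1.59 ± 0.22, the desaturase FADS2 at -1.51 ± 0.33, FASN, the fatty acid synthase gene, at -1.42 ± 0.22 and the elongase ELOVL6 at -0.90 ± 0.20. Of 19 NRF2 and oxidative stress genes 7 fell, 9 adjusted over the list alone, with AKR1C3 at -2.37 ± 0.41 and AKR1C1 at -2.26 ± 0.37 beside AKR1B10 and AKR1C2 (camera of limma, median -0.34, adjusted p = 0.000221, and adjusted p = 0.277 with an estimated correlation). AKR1C3 was at the floor in 1 late T3 array. Of 21 hypoxia and glycolysis genes 6 fell and 1 rose, 8 and 1 adjusted over the list alone (camera of limma, median -0.19, adjusted p = 0.00939, and adjusted p = 0.277 with an estimated correlation). The glucose transporter SLC2A1, NDRG1 and GPI fell, with log2 changes of -1.51 ± 0.23, -0.72 ± 0.15 and -0.58 ± 0.11, while BNIP3 rose by 0.60 ± 0.19.

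Of 22 DNA replication genes 5 rose with time in culture, 7 adjusted over the list alone (camera of limma, median 0.23, adjusted p = 0.00143, and adjusted p = 0.411 with an estimated correlation). From 1 to 72 h the median level of the list was 6.94, 6.85, 6.44, 7.38 and 7.35 in control. It was 6.59, 6.65, 7.45, 7.66 and 7.43 in RA and 6.74, 6.59, 6.63, 6.84 and 7.01 in T3. The helicase genes MCM5, MCM2 and MCM3 rose by 0.94 ± 0.23, 0.72 ± 0.17 and 0.60 ± 0.19, and PCNA by 0.65 ± 0.15. Of 13 basal keratins and hemidesmosome genes 4 fell, 5 adjusted over the list alone, PLEC at -0.81 ± 0.18, COL7A1 at -0.65 ± 0.16, the basal keratin KRT5 at -0.59 ± 0.13 and ITGA3 at -0.39 ± 0.10 (camera of limma, median -0.28, adjusted p = 0.00929, and adjusted p = 0.277 with an estimated correlation). Of 25 oxidative phosphorylation genes 7 fell, also adjusted over the list alone, among them NDUFV1 at -0.50 ± 0.13, COX5B at -0.45 ± 0.12, ATP5F1B at -0.41 ± 0.10 and UQCRC1 at -0.38 ± 0.09 (camera of limma, median -0.22, adjusted p = 0.000147, and adjusted p = 0.339 with an estimated correlation). The ribosomal genes RPL10A and RPL3 fell, at -0.48 ± 0.14 and -0.45 ± 0.13, 2 of 22, also adjusted over the list alone (camera of limma, median -0.22, adjusted p = 0.000221, and adjusted p = 0.610 with an estimated correlation). Of 14 ribosome biogenesis genes 4 fell, 5 adjusted over the list alone, RRP9 at -0.93 ± 0.25, FBL at -0.58 ± 0.11, WDR12 at -0.48 ± 0.12 and NOLC1 at -0.30 ± 0.09 (camera of limma, median -0.24, adjusted p = 0.00750, and adjusted p = 0.277 with an estimated correlation).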

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

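The tests of the control array of 4 h, of receptor activity at CYP1A1, of the other CYP1B1 probe sets, of T3 splits at an unadjusted p, of whole times split and of RA and T3 exchanged within times were chosen only after the result was seen.

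The effect of RA differed between 24 to 72 h and 1 to 4 h by a test of the difference itself, which 125 genes passed in limma. The late effect was higher for CLCA4 by 5.63 ± 0.56 (limma, adjusted p = 0.00287), CYP1B1 by 5.00 ± 0.55, KRT19 by 4.89 ± 0.63, RGCC by 3.55 ± 0.50 and TUBA1A by 2.88 ± 0.41. It was lower for ALOX12B at -6.52 ± 0.64 (limma, adjusted p = 0.00271), CYP4B1 at -6.34 ± 0.99, TGM1 at -6.25 ± 0.57, KRT1 at -5.85 ± 1.03 and LORICRIN at -5.52 ± 0.87. ALOX12B, CYP4B1 and TGM1 were at the floor in 2 late RA arrays and LORICRIN in 1, so these values are understated. Without the control array of 1, 4, 24, 48 or 72 h the count was 44, 29, 50, 40 or 52, without the RA array of 24 or 48 h 352 or 45, without the T3 array of 48 h 80, and without the time of 1, 4, 48 or 72 h 68, 34, 13 or 45.

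By list, the median difference between late and early RA effects was lower for 7 lists. It was -1.71 for envelope and differentiation genes (camera of limma, adjusted p = 8.43e-12, and adjusted p = 0.350 with an estimated correlation), with 5 of 24 genes lower. The lipid barrier had -1.60 with 2 of 11 lower (camera of limma, adjusted p = 1.74e-07, and adjusted p = 0.230 with an estimated correlation). Cholesterol biosynthesis had -0.67 with 1 of 18 lower (camera of limma, adjusted p = 1.22e-06, and adjusted p = 0.321 with an estimated correlation). Fatty acid synthesis had -0.34 with 1 of 10 lower (camera of limma, adjusted p = 0.0252, and adjusted p = 0.338 with an estimated correlation). Immediate early genes had -0.80 with 1 of 16 lower (camera of limma, adjusted p = 0.000124, and adjusted p = 0.703 with an estimated correlation). Serine proteases and their inhibitors had -0.80 (camera of limma, adjusted p = 0.000555, and adjusted p = 0.793 with an estimated correlation), and the stress response -0.41 (camera of limma, adjusted p = 0.0260, and adjusted p = 0.806 with an estimated correlation).

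The median was higher late than early for 4 lists. G2/M and mitosis had 0.63 with 1 of 18 genes higher (camera of limma, adjusted p = 0.000701, and adjusted p = 0.716 with an estimated correlation), and G1/S and DNA replication 0.45 (camera of limma, adjusted p = 0.00258, and adjusted p = 0.703 with an estimated correlation). The interferon response had 0.51 (camera of limma, adjusted p = 0.0357, and adjusted p = 0.931 with an estimated correlation) and ribosomal proteins 0.39 (camera of limma, adjusted p = 0.000205, and adjusted p = 0.822 with an estimated correlation).

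Probe sets that match several genes or none stood outside the gene tests. Of 1249 of them 110 passed under RA over all times in limma, 41 higher and 69 lower, 50 with several genes and 60 with none. Under T3 0 passed in limma, with 147 at an unadjusted p under 0.05. By Dixon's Q, the gap to the nearest array over the range, no array passed the critical value of 0.71 at either end in the 15 combinations of 3 groups and 5 array measures. With 5 arrays per group only a wide gap can pass. The RA array of 48 h came closest, at 0.678 for the GAPDH 3' to 5' ratio, 0.34 against 0.08 for the next RA array.

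Other splits of the same arrays were run for each count. Free splits part arrays of the same time, which share variation, so they alone do not settle whether chance can be excluded. For RA over all times 2 of 100 free splits, the real one included, gave as many genes as the real 531, and the highest other gave 646. That other split exchanged the RA array of 1 h and the control array of 4 h, and the next highest gave 2. The RA array of 1 h correlated with the T3 arrays of 1 and 4 h at 0.967 and 0.946, and the control array of 4 h at 0.940 and 0.958, each higher at its labelled time. For RA against T3 2 of 100 free splits were as large as the real 189. The highest other, 192, exchanged the RA array of 4 h and the T3 array of 1 h, and the next highest gave 59. The RA array of 4 h correlated with the control arrays of 1 and 4 h at 0.930 and 0.916, not higher at its labelled time. The T3 array of 1 h did so at 0.970 and 0.940, higher at its labelled time. For time in culture 1 of 100 free splits was as large as the real 1209, with a highest other of 10. For T3 over all times 100 of 100 splits gave as many as the real 0 of limma, with 782 at an unadjusted p under 0.05 and a highest other of 1, and this says nothing of chance since no split can fall below 0. The splits were too few for a share under 0.05 in 5 cases. These were whole times split for time in culture (1 of 10 splits, real 1209, highest other 565), RA and control exchanged within times (1 of 16 splits, real 531, highest other 2), RA and T3 exchanged within times (1 of 16, real 189, highest other 0), late RA (1 of 10, real 1125, highest other 0) and late T3 (10 of 10, real 0, highest other 1, with 698 at an unadjusted p under 0.05 in limma).

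T3 called 0 genes in limma, but 782 had an unadjusted p under 0.05, and 3 of 100 splits, the real one included, gave as many, with a highest other of 870. Noisier T3 arrays stay open: the spread over times of T3 minus control was 0.725 times that of RA minus control (interval 0.714 to 0.735), but the bound of 1 set for it was wrong, since the RA spread holds the change of the RA effect between early and late times, for which 125 genes passed in limma. Too few arrays stays open, since 81.8% of simulated 2-fold shifts were called (interval 78.1 to 85.1). Control arrays that deviate from both treated groups stay open: over the 782 genes the slope of the RA change on the T3 change was 0.665 (interval 0.612 to 0.718), and simulated groups without an effect gave a mean of 0.505, from 0.425 to 0.598. The intervals of the spread ratio and of the slope resampled genes, so they hold no variation between arrays or cultures. A T3 effect of under 2-fold is a candidate explanation that also stays open.

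At 4 h, 26 of 30 genes of the lists of EGFR ligands and immediate early genes were higher in RA than in control. The median was 1.27, and the median against T3 was 1.40. From 1 to 4 h the median level of the EGFR list went from 8.41 to 6.56 in control and from 8.20 to 6.09 in T3. In RA it was 7.99 and 8.03. For immediate early genes it went from 10.19 to 8.90 in control and from 10.32 to 8.39 in T3. The RA levels were 9.82 and 9.85. The difference thus came with a fall in control and T3 that the RA arrays lacked. The intervals given here for 4 h resampled genes, with 1 array per group, so they hold no variation between arrays or cultures. For these arrays a control array that alone is low is argued against, since T3 would then stand as far above control as RA. The RA median had an interval of 0.66 to 1.68, and T3 minus control had a median of -0.0596 (interval -0.463 to 0.230). Array scaling as the whole source is argued against too, as the median was 1.18 with quantile normalization (interval 0.70 to 1.75). An earlier sample on the RA array of 4 h stays open: of 113 other genes that moved by at least 2-fold the same way from 1 to 4 h in control and T3, 69 moved that way in RA, with a median share of 0.180 (interval 0.0575 to 0.323), and between the 1 h and 4 h levels of control and T3, as 0 and 1, the RA array of 4 h stood at 0.399 and that of 1 h at 0.172. An RA effect on these genes may be the source, which single arrays leave open, as they do a difference between cultures.

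CYP1A1 and CYP1B1, both targets of the aryl hydrocarbon receptor, parted at 24 to 72 h: CYP1B1 was higher in RA by 3.43 ± 0.35 (limma, adjusted p = 0.000431), while CYP1A1 had -1.67 ± 0.58 (limma, adjusted p = 0.0815). From early to late times CYP1B1 had -4.34 in control, -4.08 in T3 and 0.66 in RA, and CYP1A1 -4.14, -5.21 and -5.48. At 1 and 4 h the CYP1B1 signal was 161.4 and 105.4 in RA, 475.5 and 313.8 in control and 460.6 and 315.2 in T3. At 24, 48 and 72 h it was 170.4, 170.5 and 298.4 in RA against 39.1, 7.9 and 22.3 in control. CYP1B1 was thus lower in RA than in control early and higher late. A fault of the single CYP1B1 probe set is argued against, since the other 2 above the filter had 0.86 ± 0.31 and 2.63 ± 0.58 (limma, adjusted p of 0.170 and 0.0453), a median of 1.74, and 1 more was at the floor. Receptor activity kept up by RA would need a higher CYP1A1, and the value of -1.67 (interval -2.97 to -0.37) is lower, but it is part of the pattern itself and lies near the floor, so this stays open. An effect of RA on CYP1B1 by another route is a candidate explanation that was not tested.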

How the results depend on the processing

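T3 called 0 genes in limma over all times under the 9 alternatives run for it beside leaving out an array or time, and 0 early, late and in the difference between late and early with quantile normalization, no filter or the mean of a gene's probe sets. As first fitted 782, 463, 698 and 278 had an unadjusted p under 0.05. With quantile normalization the counts were 452 for RA over all times (424 shared), 1151 for late RA (1047 shared), 149 for RA against T3 (141 shared) and 1200 for time in culture (1130 shared). RA over all times stayed within 1.5 times its count with the stricter filter (676), the higher floor (593), the mean of a gene's probe sets (375), the variance trend (673) and a random time term (704). Time in culture did so with log2 of time (1187) and without the group term (825).

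With no filter, which tests more genes, the count was 310 for RA over all times, 44 for RA against T3, 11 for early RA and 53 for the difference between late and early RA effects, and the correlation of RA and T3 changes was 0.392. With the stricter filter, which tests fewer genes, RA against T3 called 298. The mean of a gene's probe sets gave 10 genes for early RA, and turned HR under T3 to -0.028 and PLIN2 under late RA to -0.000993. RA against T3 called 289 with the variance trend and 342 with a random time term. Without the time term RA called 226 over all times and RA against T3 93. Quantile normalization gave the ribosomal list under early RA a median of -0.020 with the camera direction turned. For these the cause was not tested, and neither was how far the number of genes tested accounts for the filter's effect. With only the compared groups, fewer arrays were fitted and the spread was estimated without the third group. This gave 17 for RA and 10 for RA against T3, and how far either change accounts for the drop was not tested. With the 5 control arrays alone time in culture gave 4. An estimated correlation in camera called 0 of the 58 list comparisons, while fry called 9 lists for RA over all times, 11 for late RA, 4 for early RA, 5 for RA against T3, 16 for time in culture and 0 for each T3 comparison. Without a shared control array the correlation of RA and T3 changes was 0.150.

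Leaving out 1 array or time gave 25 to 1094 genes for RA over all times, 30 to 957 for RA against T3, 210 to 1358 for late RA, 0 to 172 for early RA, 13 to 352 for the difference between late and early RA effects, 352 to 1264 for time in culture and 38 to 68 list comparisons. For T3 it gave 0 to 1 over all times, 0 to 1 late, 0 to 4 early and 0 to 2 for the difference. The lowest count came without the time of 48 h for RA, RA against T3, late RA and time in culture, and the highest for RA and RA against T3 without the RA array of 1 h. Under T3, HR ranged from -0.021 to 0.20, DIO2 from -0.33 to 0.12, THRB from -0.063 to 0.33 and KRT10 from -0.38 to 0.031, and the cause was not tested. Of the values of named genes under the other alternatives 771 kept direction and side of the threshold, 100 lost the call, 3 gained one and 2 turned. Of those with an array or time left out 3540 kept both, 840 lost the call, 14 gained one and 6 turned. For lists these numbers were 203, 26, 2 and 1, and with an array or time left out 980 kept both and 180 lost the call. Between 16.5% and 23.02% of signals per array were at the floor, which limits the size of falls.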

Other observations

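The tests of 48 and 72 h alone and of 4 h alone were chosen only after the result was seen.

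Interferon response genes were higher in RA at the last times of culture. Their list did not pass in camera over 24 to 72 h, the late times fixed before the data were examined. Over 48 and 72 h 16 of 29 rose and 0 fell, with a median log2 change of 0.95 (camera of limma, adjusted p = 1.10e-08, and adjusted p = 0.187 with an estimated correlation). In this fit 1 T3 term spanned 24 to 72 h, so its RA changes also drew on the T3 arrays and the arrays of 24 h. IFI44L rose by 2.78 ± 0.27 (SE, 2 RA arrays), IFIT1 by 1.74 ± 0.27 and IFIT3 by 1.72 ± 0.27. OAS1, which makes 2'-5' oligoadenylates, rose by 1.49 ± 0.24, MX1, an antiviral GTPase, by 1.28 ± 0.22 and the ubiquitin-like ISG15 by 1.09 ± 0.19. Against the control array alone, the differences at 48 and 72 h were 3.04 and 2.27 for IFI44L, 2.07 and 1.15 for IFIT1 and 2.24 and 1.06 for IFIT3. They were 1.33 and 1.45 for OAS1, 1.64 and 0.82 for MX1 and 1.28 and 0.97 for ISG15. The median of the list against control was -0.08, -0.53, -0.64, 0.98 and 0.82 at 1, 4, 24, 48 and 72 h under RA, and 0.03, -0.25, -0.00, 0.03 and -0.40 under T3. The RA array of 48 h had the highest 3' to 5' ratios of the 15, 1.04 for ACTB and 0.34 for GAPDH, and the most signals at the floor, 23.02%. The fit left 5 residual degrees of freedom and called 1358 genes in all.

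At 4 h, 3 lists of growth factor, immediate early and cytokine genes had higher medians on the RA array than on the control array, 1 array each, with their spread assumed to be that of the other arrays and 4 residual degrees of freedom. An earlier sample on the RA array of 4 h stays open, with a median share of 0.180 of the 1 to 4 h move. Taken alone, the values at 4 h are thus differences between 2 arrays and not shown to be effects of RA. Of 14 EGFR ligands and feedback genes EREG, an EGFR ligand, was higher by 5.06 ± 0.85 and the phosphatase DUSP6 by 3.77 ± 0.60 in limma, and the median was 1.70. Of 14 cytokine and NF-kB feedback genes IL1B was higher by 3.75 ± 0.56, IL36G by 2.77 ± 0.33 and TNFAIP3 by 1.93 ± 0.31 in limma, the median was 1.61, and PTGS2 had -0.97, IL18 -0.17, NFKB2 -0.15 and RELB -0.05. Of 16 immediate early genes EGR1 had 1.36 ± 0.26 and FOS 1.90 ± 0.40, and neither passed in limma, nor did any other of them, and the median was 1.05. The lists passed in camera with the preset correlation and not with an estimated one (camera of limma, adjusted p = 0.509 for each). PHLDA1 at 3.79, FOSL1 at 3.78, CXCL8 at 3.77, HBEGF at 3.70 and TGFA at 3.01 did not pass in limma. At 1 h the medians of the 3 lists against control in RA were -0.49 for EGFR ligands, 0.027 for immediate early genes and -0.27 for cytokines. DUSP6 and TNFAIP3 were below control in RA at 1 h, at -2.33 and -2.44, and thus changed sign between single arrays. EREG, IL1B and IL36G had 0.04, 0.25 and -0.07 at 1 h. From 1 to 4 h the median level of cytokine genes rose from 6.87 to 8.68 in RA. It went from 7.33 to 6.88 in control and from 7.27 to 6.47 in T3. The EGFR and immediate early lists fell in control and T3 and stayed nearly level in RA. At 24, 48 and 72 h IL1B stayed above control in RA, at 3.96, 3.16 and 2.42, and DUSP6 had 1.04, 0.24 and 0.08. EREG was at -1.34, -3.11 and -3.72, IL36G at -2.17, -1.93 and -2.23 and TNFAIP3 at -1.25, -0.56 and -0.93.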
